A study of Homo sapiens with 4 samples.

How the data were processed

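IM-9 cells were irradiated with X-rays at 80 cGy per min to 0, 1, 2 or 4 Gy and harvested after 24 h. Total RNA was reverse transcribed with random nonamers and labelled with Cy3, per the labels' protocols, so each array has 1 colour and each sample is 1 array. Groups were taken from the dose given for each sample. The labels number each sample as replicate 1 of its dose, and no dose has a further replicate.

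The authors deposited a table of processed Cy3 intensity values for 45220 features and 4 samples. Scanner data were read with Agilent Feature Extraction 8.1, per the submitters' processing notes. The background correction, the normalization and any filter behind the values are not given in the sources used here. The intensities are linear, positive and printed with 3 significant digits. They were not scaled to a common percentile, since the 75th percentiles of the arrays differ. No column went unused (0 columns). Control spots are not marked in the table and stay in. The feature numbers run from 1 to 45220 without a gap and are not gene identifiers, so no gene table could be joined to them. For that reason the 28 gene lists fixed beforehand, the sense and antisense pairs, genome positions and annotations were not analysed here. No flag tells whether a spot was above background or saturated, and the precision is limited by the number of arrays.

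Intensities were divided by the 75th percentile of their array and raised to a common floor, the highest over the arrays of the scaled 10th percentile. This floor equals an intensity of 4.07, 4.32, 3.76 and 4.24 on the 0, 1, 2 and 4 Gy arrays. Values were then put on the log2 scale. Features were kept where the mean of the 4 log2 values was at or above the median of all features, which left 22610 features, all with a geometric mean intensity of at least 87.7 and none at the floor on any array (0 features). A feature counted as higher or lower where its log2 difference from the 0 Gy array was at least 1 in size. With 1 array per dose no test between doses was run and no p-value computed. Binomial intervals and random sets of features, where given, treat features as independent and cover no variation between arrays. All sizes describe these arrays and not the conditions in general.

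The rule for named features was set before the data were examined. For probes without gene names it allows at most 2 higher and 2 lower features, and those with the largest differences at 4 Gy were taken. The robust SD given beside them is the scaled median absolute deviation of the same difference over features of like brightness (10 bins), and it holds real differences as well as noise.

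As a reference for counts, 4 unchanged arrays were simulated 100 times around each feature's mean, with deviations drawn from the differences between all pairs of real arrays in the same brightness bin. The pool holds real differences too. The procedure was tested on simulated data of all 45220 features for the 4 against 0 Gy comparison, with scaling, floor and filter run again. Seeded features were drawn from the 22610 brighter ones. This test used normal noise with the spread between the 1 and 2 Gy arrays, the closest pair. The SD of their log2 difference was 0.16, against 0.32 between the 0 and 4 Gy arrays. The rates below hold for that quieter noise and not for the real 4 against 0 Gy comparison. Of 200 features seeded at 2-fold 48.0% passed the threshold, at 3-fold 91.0% and at 4-fold 85.0%. The 2-fold seed lies on the threshold itself. Its rate follows from that placement and does not measure how well 2-fold differences are found. At 4-fold all 100 seeded higher features and 70 of 100 seeded lower ones were found, because a feature that drops can leave the brighter features.

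The grid was found from the data. Features at the lowest value on all 3 irradiated arrays varied smoothly on the 0 Gy array, and a row width of 85 gave the highest correlation between neighbouring rows (r = 0.897 over 769 pairs of features), which makes 532 rows. The layout is inferred and not stated in the labels.

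Alternatives fixed before the data were examined were the values as deposited, median centring, quantile normalization, cyclic loess, no filter, a filter keeping the brightest 25% of features, no floor, a floor at the 25th percentile, and each dose against the mean of the other 3 arrays. Alternatives added after seeing the data were removal of the local median difference in a window of 15 by 15 grid positions, leaving out 3 rows and columns at the border, leaving out grid columns 1 to 28, and a brightness filter on the 0 Gy array alone, on the 1 and 2 Gy arrays alone or on the brighter of the 0 and 4 Gy arrays. For the 4 Gy counts and the dose orders, no filter and the filters that use the 0 Gy array alone or the brighter of the 0 and 4 Gy arrays were also combined with leaving out those columns. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for quantile and cyclic loess normalization.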

Results

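IM-9, a human B lymphoblastic cell line described as highly sensitive to ionizing radiation, was exposed to X-rays at 0, 1, 2 or 4 Gy and collected 24 h later. Total RNA was labelled with Cy3 and hybridised to a custom 1-colour microarray designed with sense and antisense probes for human genes. The series held 4 arrays, 1 array per dose, so no value below has a spread between replicates, a standard error or a p-value. Each array gave an intensity for the same 45220 features, identified by a running number only. No gene, strand, probe sequence or genome position is attached to these numbers in the sources used here. Features are therefore described by number and by intensity, and which of them report sense and which antisense transcripts was not analysed here.

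Signal was close to even over the 4 arrays. The median intensity was 90.7 at 0 Gy, 91.3 at 1 Gy, 78.9 at 2 Gy and 93.8 at 4 Gy, and the 75th percentile was 453, 481, 418 and 472. The summed intensity was lowest at 2 Gy, at 0.90 of that on the 0 Gy array, and was 1.00 of it at 1 Gy and 0.97 of it at 4 Gy. The low end differed. On the 1, 2 and 4 Gy arrays 5795, 7159 and 6191 features shared the lowest value of the array (3.14, 3.61 and 3.36), whereas 22 features did so on the 0 Gy array. After scaling, 22610 features had a mean over the 4 arrays at or above the median of all features. These are called the brighter features and the rest the dim features, and the comparisons rest on the brighter features unless said otherwise.

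The untreated array was the farthest from the 4 Gy array. Across the brighter features the SD of the log2 difference was 0.23 between 0 and 1 Gy, 0.27 between 0 and 2 Gy and 0.32 between 0 and 4 Gy. The closest arrays were those of 1 and 2 Gy, with 0.16, and the 2 and 4 Gy arrays differed by 0.21. Pearson's r across features, which are not independent replicates, ran from 0.9893 for 0 against 4 Gy to 0.9973 for 1 against 2 Gy. Most transcripts measured by these features differed little, since the quartiles of the log2 difference at 4 Gy were -0.21 and 0.17.

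The 0 Gy array carried raised signal along one side, which bears on every comparison with it. Placed on a grid of 532 rows by 85 columns, 1711 dim features were at least 2-fold above all 3 other arrays on the 0 Gy array, against 209, 149 and 285 features on the 1, 2 and 4 Gy arrays. Of the 1711 features, 1497 (87.5%) lay in grid columns 1 to 28, which held 32.8% of the dim features. The dim features there read 8.37 intensity units higher, at the median, on the 0 Gy array than on the scaled mean of the irradiated arrays. The same offset was 0.22 in columns 29 to 56 and 0.30 in columns 57 to 85. Counts are therefore also given for columns 29 to 85 alone, a choice made after the data were seen. Those columns were not even for dim features either, since higher ones outnumbered lower ones there at every dose against 0 Gy.

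**Figure D1:**
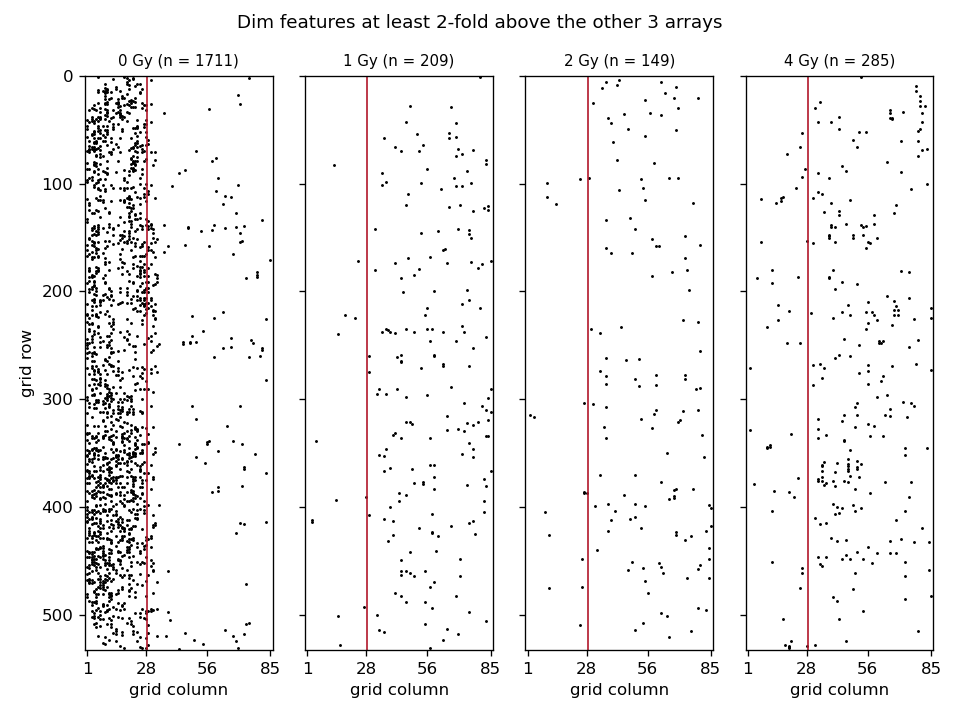
Position, by grid column (x axis) and grid row (y axis), of dim features whose scaled intensity was at least 2-fold above that on the other 3 arrays, with 1 panel per array and 1 point per feature; the red line follows column 28. On the 0 Gy array 1497 of 1711 such features lay in columns 1 to 28, against 13 of 209 at 1 Gy, 16 of 149 at 2 Gy and 47 of 285 at 4 Gy.

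The first comparison asked which transcripts were higher or lower after 1 Gy. At this dose 19 features were at least 2-fold higher and 25 at least 2-fold lower than at 0 Gy, together 0.19% of the brighter features. Columns 29 to 85 alone held 12 and 5 such features. Both totals were under the averages of 100 simulations of 4 unchanged arrays, which gave 35.0 features higher and 33.6 lower at 1 Gy. The simulated spread is pooled over all pairs of arrays, 0 against 4 Gy included, and is not that of 0 against 1 Gy. Lying under it does not show that no feature changed at 1 Gy. The direction of the split depended on scaling: 43.2% of the features 2-fold apart were higher in the main setting, 62.5% (35 higher, 21 lower) in the values as deposited, and 59.6% (31 higher, 21 lower) with each array centred on its median. It depended more on the brightness filter: the share was 10.0% (12 higher, 108 lower) with a filter on the 0 Gy array alone. Here and below, that filter favours features bright on the 0 Gy array, and so lower ones, by construction. With no filter the share was 25.5% (1040 higher, 3042 lower), and in the brightest 25% of features 100.0% (7 higher, 0 lower). At 1.5-fold, 195 features were higher and 273 lower.

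At 2 Gy, 82 features were at least 2-fold higher and 38 at least 2-fold lower, 0.53% of the brighter features. The simulated unchanged arrays gave at most 51 higher and 48 lower. On the real arrays, 55 of the higher and 8 of the lower features lay in columns 29 to 85. Over all columns, higher features made up 68.3% of those 2-fold apart. This share was 46.4% (52 higher, 60 lower) in the values as deposited, in which the 75th percentile of the 2 Gy array lay at a log2 difference of -0.116 from that of the 0 Gy array. It was 79.0% (109 higher, 29 lower) with median centring. It depended more on the brightness filter: the share was 26.7% (52 higher, 143 lower) with a filter on the 0 Gy array alone. With no filter it was 23.9% (1082 higher, 3448 lower). It was 77.7% (94 higher, 27 lower) with a filter on the 1 and 2 Gy arrays alone. That filter leaves out the 0 Gy array and so favours higher features by construction, here and below. With the filter keeping only the brightest features the share was 94.1% (32 higher, 2 lower). Of the 19 features higher at 1 Gy, 15 were also higher at 2 Gy. Both comparisons use the same 0 Gy array, and simulated unchanged arrays that share it gave 8.5 such features on average and at most 16. The simulated lists had other lengths, on average 35.0 features higher at 1 Gy and 34.3 at 2 Gy. The counts are therefore not directly comparable, and how much of the overlap the shared control gives was not decided. Independent lists would share 0.07.

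After 4 Gy the higher group was the larger among the brighter features. At this dose 181 features were at least 2-fold higher and 41 at least 2-fold lower, 0.98% of the brighter features, where the simulated unchanged arrays gave at most 54 higher and 53 lower. In columns 29 to 85 the counts were 122 and 17. The share that was higher was 81.5% in the main setting and between 81.2% and 86.2% under every other scaling tried. It depended on the brightness filter: it was 50.6% (125 higher, 122 lower) with a filter on the 0 Gy array alone, 69.9% (230 higher, 99 lower) with a filter on the brighter of the 0 and 4 Gy arrays and 34.7% (1522 higher, 2867 lower) with no filter. In columns 29 to 85 these became 67.3% (76 higher, 37 lower), 83.0% (156 higher, 32 lower) and 65.1% (1338 higher, 717 lower). Without a filter 1216 of the higher and 700 of the lower features in these columns were dim. Among dim features there the ratio of lower to higher was 0.59 at 1 Gy, 0.83 at 2 Gy and 0.58 at 4 Gy. The unfiltered excess of higher features in these columns was thus not particular to 4 Gy. Of the 82 features higher at 2 Gy, 75 were also higher at 4 Gy, against at most 19 in simulated unchanged arrays with a shared control and 0.66 for independent lists. The simulated lists were shorter, with 34.3 and 35.5 features on average, so the count of 19 is not directly comparable. At least 3-fold differences numbered 35 higher and 7 lower, and at least 4-fold differences 13 higher and 4 lower. The 181 higher features were spread over the grid, with 32.6% of them in columns 1 to 28, which held 33.0% of the brighter features. Of the 41 lower features, 58.5% lay in those columns, where the 0 Gy array was raised.

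**Figure D2:**
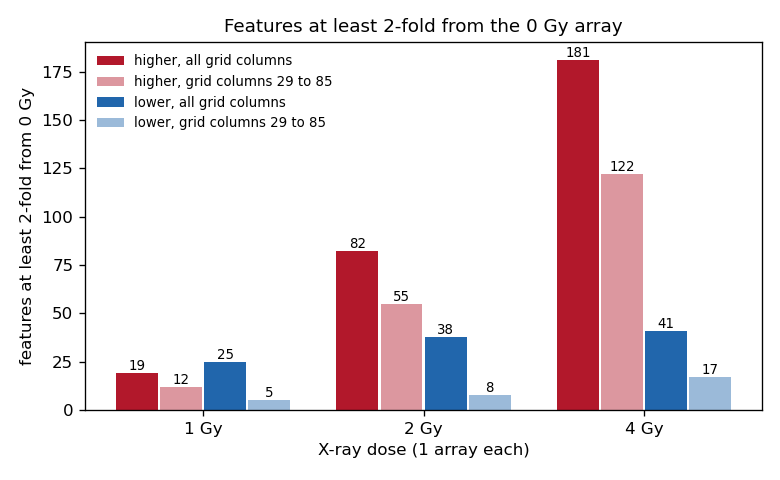
Number of brighter features (y axis) at least 2-fold higher (red) or lower (blue) than on the 0 Gy array at each X-ray dose (x axis), over all grid columns (dark bars) and over columns 29 to 85 (light bars), with 1 array per dose. Higher features increased from 19 to 82 and 181 over the doses, and lower features went from 25 to 38 and 41, or from 5 to 8 and 17 in columns 29 to 85.

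The features higher at 4 Gy also differed between the 1 and 2 Gy arrays. The 181 features higher at 4 Gy had a median difference from 0 Gy of 0.61 log2 units at 1 Gy, 0.93 at 2 Gy and 1.21 at 4 Gy, or 1.53-fold, 1.91-fold and 2.31-fold. All 3 medians are raised by the selection, since they share the 0 Gy array. Features selected in the same way from simulated unchanged arrays had medians of 0.42, 0.44 and 1.21 on average, and up to 0.86 at 1 Gy and 0.97 at 2 Gy. The simulated sets were smaller, with 35.5 features on average and at most 54, so their medians scatter more than those of 181 features. The medians by themselves therefore do not decide whether selection gave them. The 1 and 2 Gy arrays entered the selection only through the brightness filter, and 175 of the 181 features (96.7%) were higher at 2 Gy than at 1 Gy, against 48.3% of all brighter features and at most 76.19% of the selected features in the simulations. With a filter that leaves those arrays out the share was 96.8% (0 Gy array alone) or 92.2% (brighter of the 0 and 4 Gy arrays), and with no filter 806 of 1522 such features were higher at 2 than at 1 Gy, against 41.3% of all features. The median step between those arrays was 1.26-fold. The same held for 119 of 122 features in columns 29 to 85, which were higher at 2 than at 1 Gy. The lower features showed less of a gradient: 24 of 41 (58.5%) were lower at 2 than at 1 Gy, against 51.7% of all brighter features. In columns 29 to 85, 10 of the 17 lower features were lower at 2 than at 1 Gy, and their median differences from 0 Gy were -0.38, -0.54 and -1.14 log2 units at 1, 2 and 4 Gy. Over all columns the 41 lower features had medians of -0.69, -0.82 and -1.20. Lower features selected from simulated unchanged arrays had -0.76, -0.75 and -1.20 on average, and as little as -0.35 at 1 Gy and -0.32 at 2 Gy. These simulated sets also cover all columns, with 33.9 features on average, and were not drawn for columns 29 to 85 alone.

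Of the brighter features at 4 Gy, the 2 with the largest positive and the 2 with the largest negative difference are named here. Feature 19170 had an intensity of 54.8 at 0 Gy, 223 at 1 Gy, 320 at 2 Gy and 526 at 4 Gy. After scaling it was 3.83-fold, 6.33-fold and 9.21-fold higher, first among the brighter features at 1 and 4 Gy and second at 2 Gy. Feature 18655 went from 171 to 582, 857 and 1600, and was 3.21-fold, 5.43-fold and 8.98-fold higher. For features of like brightness the robust SD of the difference at 4 Gy was 0.29 log2 units for the former and 0.27 for the latter, beside their differences of 3.20 and 3.17. Feature 20919 had an intensity of 1140 at 0 Gy and 48.9, 40.7 and 97.9 at 1, 2 and 4 Gy, so it was 24.75-fold, 25.85-fold and 12.13-fold lower. Feature 7566 read 694 at 0 Gy and 120, 113 and 128 after irradiation, 6.14-fold, 5.67-fold and 5.65-fold lower. The same robust SD was 0.33 for feature 20919 and 0.29 for feature 7566, beside differences of -3.6 and -2.5. All 4 features were picked as extremes, so that they exceed this spread follows from the choice. Both lower features sat in the raised part of the 0 Gy array, in grid columns 9 and 1, and neither was lower at 4 Gy than at 1 Gy.

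**Figure D3:**
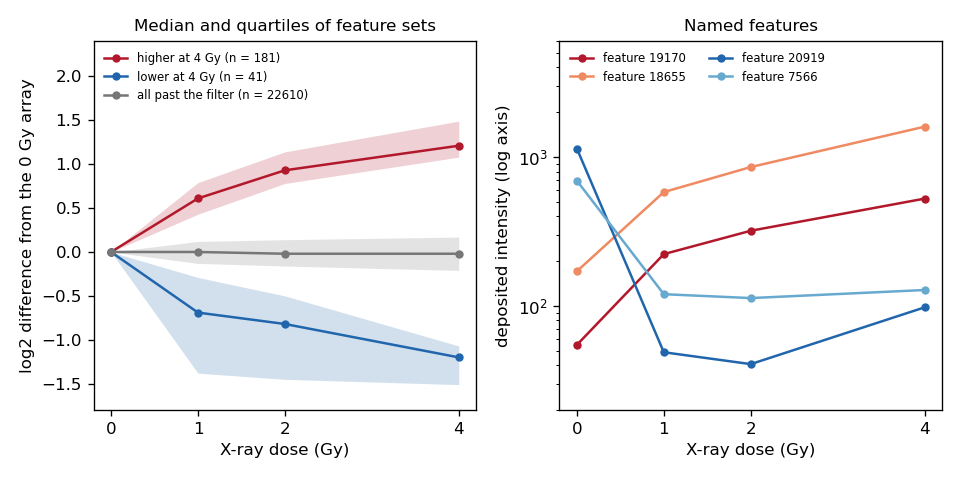
Left: median log2 difference from the 0 Gy array (y axis) against dose in Gy (x axis) for the features at least 2-fold higher or lower at 4 Gy and for all 22610 brighter features, with bands from the lower to the upper quartile. Right: deposited intensity on a log axis against dose for the 4 named features, 1 array per point. The 181 higher features had medians of 0.61, 0.93 and 1.21, where selection from simulated unchanged arrays gave 0.42, 0.44 and 1.21, and features 20919 and 7566 were lower at 1 Gy than at 0 Gy and did not decrease further by 4 Gy.

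Among the brighter features only a small group stood 2-fold from 0 Gy at all 3 doses. There were 14 features higher and 14 lower throughout. Simulated unchanged arrays that share their control gave on average 6.6 and 10.8 such features and at most 16 and 19. This does not decide whether a single control array produces such counts. The simulated deviations come in part from the 0 Gy array's own differences, these features among them. The simulated lists also had another length, on average 35.0 features higher at 1 Gy where the real list held 19. The number of higher features depended on scaling. It was 22 in the values as deposited and with median centring and 17 after quantile normalization. Both numbers depended on the brightness filter: there were 9 higher and 54 lower with a filter on the 0 Gy array alone. With no filter there were 271 higher and 1725 lower. A filter on the 1 and 2 Gy arrays alone gave 16 higher and 11 lower, and the filter keeping only the brightest features 7 and 0. The simulations were not repeated for any of these settings. The 2 groups differed in shape and place. The 14 higher features had medians of 1.16, 1.76 and 1.93 log2 units at 1, 2 and 4 Gy, and 13 of them were higher at 4 than at 1 Gy. The 14 lower features had medians of -1.74, -1.69 and -1.55, and 13 of them lay in grid columns 1 to 28, which leaves 1 in the other columns.

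The design of rising doses asks whether intensities follow the dose. The 4 arrays can be put in 24 orders, and a feature without any relation to dose falls into each with equal chance if the arrays are equally noisy. The order 0, 1, 2, 4 Gy from dimmest to brightest held 162 features with at least 2-fold between the ends, the most of the 24 orders. The reverse order held 17, and the other 22 orders held at most 14, with a median of 3.5. With no filter the upward order was not the fullest, with 491 features against 714 in another order. Simulated unchanged arrays gave at most 20 features in the upward order and at most 17 in the downward order. In columns 29 to 85 the upward order held 111 features and the downward order 9, with at most 11 in any other order. A rank of 1 among 24 is the smallest share, 4.2%, that 4 arrays can give.

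With smaller differences counted, the downward order also held more features than the remaining orders in the main setting. At 1.5-fold between the ends, 590 features were ordered upwards with dose and 333 downwards, and no other order held more than 151. These numbers were 419, 198 and 74 in columns 29 to 85. This depended on processing: in the values as deposited 453 features were ordered upwards and 189 downwards at 1.5-fold, against 448 in the fullest of the other orders, and with no filter 1214 and 1017, against 1169. With no limit on size, 2314 features (10.2%) were ordered upwards and 2733 (12.1%) downwards, against at most 1358 and a median of 850 in the other 22 orders. The pattern at any size held under quantile and cyclic loess normalization. It did not hold in the values as deposited, where 886 features were ordered upwards, 992 downwards and 2580 in the fullest of the other orders, or with median centring, where the numbers were 2046, 1911 and 2248.

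**Figure D4:**
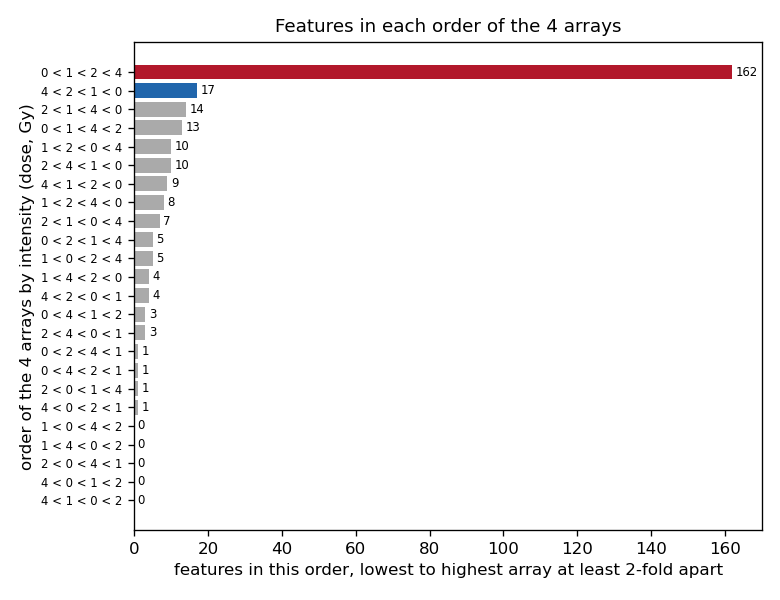
Number of brighter features (x axis) whose 4 intensities fell in each of the 24 possible orders of the arrays, from dimmest to brightest (y axis, doses in Gy), with at least 2-fold between the ends. The order that follows the dose upwards (red) held 162 features, the reverse (blue) 17, and the others (grey) 14 or fewer.

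Differences between arrays that were not shared were also compared. Across the brighter features the 4 minus 0 Gy difference correlated with the 2 minus 1 Gy difference at r = 0.375, and the 2 minus 0 Gy difference with the 4 minus 1 Gy difference at r = 0.236. The 1 minus 0 Gy difference did not follow the 4 minus 2 Gy difference, with r = -0.073. In the brightest 25% of all features the 3 values were 0.526, 0.358 and 0.001, and with no filter they were 0.108, 0.009 and -0.095. These 3 correlations are the ones computed, run across features of the same 4 arrays, and carry no p-value. They are not separate results, since by algebra the covariances of any 2 of these pairs of differences fix that of the third. Of the 19 features higher at 1 Gy, 15 (78.9%) were higher at 4 than at 2 Gy, against 46.5% of all brighter features. Of the 25 features lower at 1 Gy, 17 (68.0%) were also higher at 4 than at 2 Gy.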

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

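No paired analysis was possible because each dose has 1 array. The other settings meant for gene lists and for sense and antisense pairs were not run, since the features carry no names. Of 235 values recomputed for counts and correlations, 170 stayed within 1.5-fold (counts) or 0.1 (correlations) of the main value, and all 84 recomputed differences of the 4 named features kept their sign and moved by less than the spread of features of like brightness. Some of these values could not move. Leaving out the floor changes nothing where no brighter feature lies at it. Correlations cannot change where arrays are only shifted, as in the values as deposited and with median centring. The upward dose order at 2-fold held more features than any other order in the settings where orders were counted, except with no filter over all columns, where it held 491 and the fullest other order 714. Orders do not depend on the array compared against, so they were not counted for the comparison with the mean of the other 3 arrays. Scaling moved the low doses. In the values as deposited, 35 features were higher at 1 Gy, 52 higher and 60 lower at 2 Gy, 22 higher at all 3 doses, 189 ordered downwards at 1.5-fold, and 886 upwards and 992 downwards at any size. Median centring gave 31 higher at 1 Gy and 22 higher at all 3 doses. Signal limits the dim features most. With no filter, 1040 features were higher and 3042 lower at 1 Gy, 1082 and 3448 at 2 Gy, 1522 and 2867 at 4 Gy, and 271 and 1725 at all 3 doses. Dose orders then held 491 upwards and 423 downwards at 2-fold and 1214 and 1017 at 1.5-fold, and the correlations fell to 0.009 (2 minus 0 with 4 minus 1 Gy) and 0.108 (4 minus 0 with 2 minus 1 Gy). Keeping the brightest 25%, which leaves fewer features to count, gave 7 higher and 0 lower at 1 Gy, 32 and 2 at 2 Gy, 61 and 8 at 4 Gy, and 7 and 0 at all 3 doses. Dose orders there held 57 upwards and 7 downwards at 2-fold, 237 and 182 at 1.5-fold, and 1215 and 1818 at any size, and the same 2 correlations were 0.358 and 0.526. Against the mean of the other 3 arrays, 6 features were higher and 7 lower at 1 Gy, 2 and 4 at 2 Gy, and 32 and 4 at 4 Gy. That comparison sets irradiated arrays against each other and so shrinks graded differences by construction. Leaving out grid columns 1 to 28 left 12 higher and 5 lower at 1 Gy, 8 lower at 2 Gy, 17 lower at 4 Gy, 9 higher and 1 lower at all 3 doses, and 9 ordered downwards at 2-fold and 198 at 1.5-fold. A filter on the 0 Gy array alone, which selects features raised there, gave 12 higher and 108 lower at 1 Gy, 52 and 143 at 2 Gy, 122 lower at 4 Gy, 9 higher and 54 lower at all 3 doses, and 44 ordered downwards at 2-fold. A filter on the brighter of the 0 and 4 Gy arrays gave 99 lower at 4 Gy. Without columns 1 to 28, a filter on the 0 Gy array gave 76 higher at 4 Gy, and no filter 1338 higher and 717 lower. Apart from the constructions named, the cause of these moves was not tested.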

Other observations

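The tests of the graded group against brightness trends, position, scaling and a filter on the 1 and 2 Gy arrays, and of the distances within the lower group, were written down before their results were seen. The share of higher features at 2 against 1 Gy, the counts and places of single raised spots, the other filters, the test of neighbouring spots and all tests of the raised side were chosen after. A few features outside the comparisons above were at the floor at 0 Gy and as bright as the brighter features after irradiation, namely 1 at 1 Gy, 1 at 2 Gy and 2 at 4 Gy, and the reverse held for 2, 4 and 1 features.

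The pattern most worth following is the excess of features higher at 4 Gy. After cyclic loess the ratio of higher to lower features was 4.6 (184 to 40) and after removal of local medians 5.85 (193 to 33), and equal counts would need a shift of 0.165 log2 units where the tried scalings differ by 0.059, which argues against a brightness trend, local position or scaling as the whole source. In columns 29 to 85 the brightness filter is argued against as the whole source too: a filter on the brighter of the 0 and 4 Gy arrays, which treats both directions alike, gave 4.88 there (156 to 32, 95% binomial interval 3.32 to 7.37, which takes features as independent and covers no variation between arrays), and one on the 0 Gy array 2.05 (76 to 37). In columns 1 to 28 its part stays open, since the former gave 1.1 (74 to 67, interval 0.78 to 1.56) where the 0 Gy array is raised. Over all columns the same filters gave 230 to 99 and 125 to 122, and one on the 1 and 2 Gy arrays 4.4 (185 to 42), which decides little because it also drops features bright at 0 Gy only. A response that grows with dose is a hypothesis for the higher features, 96.7% of which were higher at 2 than at 1 Gy against 48.3% overall. Over all brighter features the 1 minus 0 Gy and 4 minus 2 Gy differences did not go together (r = -0.073), which a graded response of most features would not give. An order of culture, labelling or hybridisation that ran with dose was not tested, since each dose has 1 array.

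The 14 features lower at all 3 doses, which include both features named as lowest, may be a product of the untreated array. They were lower at 1 Gy and did not drop further, with 10 of the 14 higher at 4 than at 1 Gy, and 92.9% of them lay in grid columns 1 to 28, against 33.0% of all brighter features. The even raised signal of that side is argued against as their source, since 3451 other features of like brightness there were shifted at 1 Gy by a median of -0.14 log2 units (robust SD 0.25) relative to the other columns, against -1.74 for the 14. A defect over neighbouring spots is argued against by the 53 brighter features next to them on the grid, shifted by -0.08 (robust SD 0.2) relative to the rest of columns 1 to 28. Their distance to the nearest fellow decides nothing: its median of 23.2 grid steps lay between the 5th percentile of 18.6 and the median of 29.8 in 10000 random sets, and missing that percentile does not exclude clustering, so the bound set beforehand was too weak. Single raised spots at a like rate on every array are argued against too, since the 1 and 2 Gy arrays held 3 and 1 such features and the 0 Gy array 14. Single bright spots that fell mostly on that side of the 0 Gy array stay open: 8 of 12 dim features with a like excess lay there (66.7%, 95% binomial interval 34.9 to 90.1), against 32.8% of all dim features. A real drop that is complete at 1 Gy is argued against for the group by the 92.9% in those columns, against 33.0% of all brighter features. This holds if the place of a probe is unrelated to its response, which cannot be checked without probe names. For single features of the 14 a real drop stays open.

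Among dim features, lower ones outnumbered higher ones 2.95-fold at 1 Gy, 3.41-fold at 2 Gy and 2.11-fold at 4 Gy against 0 Gy. Outside grid columns 1 to 28 the ratio was between 0.58 and 0.83. The excess of lower ones thus lay on the raised side of the 0 Gy array, which goes with raised signal there as its source. In columns 29 to 85 higher dim features outnumbered lower ones. The counts were 960 to 566 at 1 Gy, 927 to 774 at 2 Gy and 1216 to 700 at 4 Gy. A raised side alone does not account for that reversal, and its cause was not tested. Transcripts lowered by a like fold and placed in columns 1 to 28 are argued against by the brighter features there. Their median difference at 1 Gy, relative to columns 29 to 85, was -0.06 log2 units where that of the dim ones was -0.58. Whether a different background handling of the whole 0 Gy array adds to it cannot be told apart: the number of lower dim features at 4 Gy was 0.94 times that at 1 Gy, as such a difference would give, but the 2 and 1 Gy arrays also differed, with a ratio of 1.59. A list of dim transcripts lowered by X-rays drawn from this table without regard to position would therefore consist mostly of features from that side, 2126 of 2826 at 4 Gy.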
